A study of Mus musculus with 9 samples.

How the data were processed

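Expression was measured in neonatal Swiss mouse ovaries taken at postnatal day 3 to 4 and cultured for 96 hours (4 days) with 0.01% acetone as the vehicle, with DMBA (7,12-dimethylbenz[a]anthracene) at 50 nM or with BaP (benzo[a]pyrene) at 1 uM. Each group holds 3 arrays, 9 in all, of an Illumina mouse Ref-8 beadchip. The labels do not say whether the arrays of a group came from separate animals, pools or cultures, so p-values measure the spread between these samples, which may be technical.

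Per the file headers, the first deposited table holds non-normalized probe intensity values on a linear scale, with no detection p-values. What the scanner software subtracted is not given in the sources used here. A deposited table of normalized values holds log2 expression of the same arrays, and lumi is named in the submitters' processing notes. The authors' deposited reports hold, for each compound, a linear ratio of acetone over compound and an unadjusted p-value per probe, from a test their sheet calls ANOVA. The model behind those p-values is not given in the sources used here. A 3-group analysis of variance of the deposited log2 values ranked the probes alike (Spearman rho 0.977 for DMBA and 0.978 for BaP across probes) but gave larger values: the median of the deposited p over it was 0.583 for DMBA and 0.459 for BaP, among probes under 0.05. In the authors' deposited table for DMBA, the sheet named for a fold of 1.5 holds 2941 probes under an unadjusted p-value of 0.05, and the sheet named for that p-value holds 110 probes that also pass the fold, so these sheets look exchanged. The authors' deposited table lists 110 probes as differentially expressed for DMBA, 96 higher and 14 lower, and 205 for BaP, 139 higher and 66 lower. In the authors' deposited table for BaP, 31 p-value cells hold clock times, and 31 paired probes have a date in place of a gene symbol in the authors' deposited table. The probes with dates were named by accession. A further column type in the deposited reports, gene numbers per ontology term, was not tested here.

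The value tables name probes and the deposited reports name genes, with no key between them in the tables used. Each probe was therefore paired with the report row whose log2 ratios for both compounds matched the differences of its group means, within 0.0001 and with the next row at least 5 times farther. This paired 25649 of 25697 probes, with a median distance of 4.5e-06 against 9.63e-04 for the next nearest row, and 48 probes were left out. The pairing was checked on a quantity it did not use, the spread implied by the deposited p-value, among probes with a log2 ratio over 0.1 in size. That spread correlated with the spread between arrays at a Spearman rho of 0.897 for DMBA and 0.868 for BaP in the rows taken, against 0.199 and 0.194 in the next nearest rows. Names were updated through the mouse reference table of assembly GRCm38.p6. Of the paired probes, 23692 were named by accession, 852 by current symbol and 434 by synonym, while 671 kept the deposited name.

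Signals were corrected with normexp (offset 50), quantile normalized over the 9 arrays and put on the log2 scale. With no detection p-values, no filter was applied. For each of 17889 genes the probe with the highest mean was tested, so isoforms that other probes measure were not used, and values of other probes are given for some of the genes described. Each comparison was fitted on its own 6 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Adjusted p-values throughout come from limma. Joins and plots used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. A total of 27 gene lists was tested with camera (preset correlation 0.01), with camera and an estimated correlation, and with fry. The median of a list and its camera test had opposite signs in 17 of 81 tests, of which 0 passed the threshold. The comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule takes, per comparison, the 10 largest increases and 10 largest decreases among called genes whose groups do not overlap, leaving out clone and prediction names. It adds up to 4 members of each list that passed or had at least 2 called members, and a panel of 20 genes, 19 of which were on the array. Some genes the rule takes are not reported here.

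Arrays differed in brightness. The median signal was 105.8 to 133.7 on acetone arrays, 105.2 to 126 on DMBA arrays and 94.7 to 104.1 on BaP arrays. The number of arrays limits the precision, with a median standard error of a log2 difference of 0.088 for DMBA, 0.087 for BaP and 0.094 between the compounds.

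The fit was tested on simulated data, 20 draws per comparison with 200 of 17889 genes changed. With the spread measured in each group, a log2 change of 1 was recovered in 93.2% of genes for DMBA, 98.7% for BaP and 93.8% between the compounds, and a change of 0.5 in 59.8%, 66.3% and 53.0%. False calls made up 8.79% of calls for DMBA, 5.42% for BaP and 8.29% between the compounds, above the nominal level on average, with ranges over the draws of 5.2 to 12.8%, 2.19 to 9.38% and 5.71 to 14.1%. With a pooled spread in both groups, as the model assumes, these shares were 4.51%, 3.01% and 3.96%. The called genes of both comparisons that involve DMBA may thus hold more false calls than the threshold states.

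Alternatives were the deposited values, no background correction, median scaling, brightness filters, the mean of probes, every probe, all arrays in one fit, array weights, a replicate block, a plain test of the kind the deposited sheets name, fold thresholds, a trended robust fit and leaving out each replicate. A slide block was not run because the columns give no slide.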

Results

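DMBA and BaP are polycyclic aromatic hydrocarbons, combustion and tobacco smoke chemicals that cells convert to DNA-binding metabolites. The series asked which transcripts change in cultured neonatal mouse ovaries, organs rich in primordial follicles, after exposure to either compound. Levels of 17889 genes were compared among 3 acetone, 3 DMBA (50 nM) and 3 BaP (1 uM) arrays. The first principal component (31.1% of variance) placed the acetone arrays at -9.56 to -11.8, the DMBA arrays at -1.56 to -4.61 and the BaP arrays at 12.7 to 16.7. DMBA replicate 3 stood apart on the second component, at -23.9, and its deviation from its group mean had an SD of 0.153 log2 units, against 0.079 to 0.123 on the other arrays.

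With DMBA, the cell cycle inhibitor gene Cdkn1a rose most, 2.50-fold (log2 1.32, SE 0.12, adjusted p = 0.00123), from 8.75 ± 0.10 to 10.07 ± 0.27 (mean ± SD of log2 signal, n = 3). The p53 target Phlda3 rose by 0.85, the antigen-presenting molecule gene H2-Ab1 by 1.10 and the complement genes C1qb and C1qc by 0.88 and 0.65. Padi1, a protein-modifying enzyme gene, fell by 1.70 (SE 0.10, adjusted p = 9.16e-05), and the oocyte genes Oosp1 and Bmp15 fell by 0.78 and 0.55. In all, 186 genes passed, 128 higher and 58 lower, and 91 of them changed at least 1.5-fold. Over all genes tested, the arrays of both groups did not overlap in 15.7%, against 10% by chance.

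Other large increases with DMBA were those of Hnrnpa2b1 (1.28), an RNA-binding protein gene, Kctd14 (1.20), Tsc22d1 (1.17), Adss (1.15), Nipsnap2 (1.12), Eif4g2 (1.12), Slc25a17 (1.11) and the chaperone gene Calr (1.10), all log2 values with standard errors from 0.12 to 0.16. Dimmer probes of Hnrnpa2b1 gave -0.06 and 0.02, and single dimmer probes gave 0.01 for Eif4g2, 0.10 for Tsc22d1, 0.49 for Kctd14 and -0.11 for Gabrp. Those at 0.02, 0.10 and -0.11 had low mean levels of 5.93, 6.51 and 6.19, where little of a change can show. Dimmer probes of Cdkn1a, at mean levels of 8.13 and 7.76, gave 0.84 and 0.74. Large decreases were those of the cell-surface gene Tenm4 (-1.21), Taf15 (-0.94), Dynlrb2 (-0.82), Ttc27 (-0.75), the matrix protease gene Mmp9 (-0.74), Sectm1b (-0.73), Gabrp (-0.70) and Sdc4 (-0.68).

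Of 40 measured p53 targets, 2 rose and none fell with DMBA (6 and 0 adjusted over the list alone), and the list was higher than other genes (camera adjusted p = 1.09e-05). Mdm2, the p53 regulator, was at -0.10 and the pro-apoptotic Bax at 0.15, neither past the test. Of 34 interferon response genes, 3 rose, namely the antiviral Rsad2 (0.57), Ifit3 (0.53) and Igtp (0.52), with 5 adjusted over the list alone (camera adjusted p = 1.09e-05). Of 27 macrophage and leukocyte genes, C1qb and C1qc rose (5 adjusted over the list alone, camera adjusted p = 9.79e-04). Of 23 inflammation genes, the chemokines Cxcl10 and Ccl5 both rose by 0.56 (4 adjusted over the list alone, camera adjusted p = 0.0168). None of 34 granulosa genes rose and 1, Greb1 (-0.43), fell, with 2 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.0148). Without DMBA replicate 3, 6 p53 targets, 6 interferon response, 5 macrophage and 4 inflammation genes rose, and 2 granulosa genes rose and 3 fell. With an estimated correlation none of these lists passed: the adjusted p = 0.0636 for p53 targets and interferon response, 0.128 for macrophages and 0.148 for inflammation and granulosa genes with an estimated correlation. The correlations estimated were -0.018 for p53 targets, -0.022 for interferon response, 0.012 for macrophages, -0.044 for inflammation and 0.0015 for granulosa genes. Beside the preset 0.01, these p-values did not rise through a large correlation of members.

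Among 13 genes of the aryl hydrocarbon receptor battery, which includes enzymes that metabolize such compounds, limma called 0 with DMBA and 1, Ugt1a6a (0.62), adjusted over the list alone, beside 1828 genes of all at an unadjusted p under 0.05. The list was higher (camera adjusted p = 0.028), with adjusted p = 0.18 with an estimated correlation. Cyp1a1 was at 0.03, Cyp1b1 at 0.07 and Ahrr at 0.03. Cyp1a1 lay at percentile 12.4 of levels, near the lowest signals of the array. Of 23 unfolded protein and heat shock genes, Calr and Hspa8 (1.09) rose, also adjusted over the list alone (camera adjusted p = 0.0329), with adjusted p = 0.451 with an estimated correlation. Under median scaling this list had a median of -0.037 (adjusted p = 0.15), and the calls of inflammation (adjusted p = 0.141) and of hypoxia and glycolysis (adjusted p = 0.185) were lost. Of 28 hypoxia and glycolysis genes limma called 0, over all genes and adjusted over the list alone, while the list was higher (camera adjusted p = 0.00409), with adjusted p = 0.128 with an estimated correlation. Without DMBA replicate 3, limma called 3 of these genes higher, 1 of the aryl hydrocarbon receptor battery higher and 5 oocyte genes lower. Of 51 oocyte genes, Spin1 rose by 0.67, Oosp1 and Bmp15 fell, and 2 rose and 5 fell adjusted over the list alone, which did not pass (camera adjusted p = 0.378). Gdf9 (-0.18), Zp3 (0.19), Ddx4 (0.31), Foxl2 (0.33), Foxo3 (0.04), Akt1 (0.03), Actb (0.09) and Gapdh (0.12) did not pass, and median scaling put Actb at -0.054 and Gapdh at -0.032. Foxo3 and Akt1 lay near the lowest signals, at mean levels of 6.01 and 6.14 beside 5.92 for Cyp1a1. The 4 dimmer probes of Actb went both ways, at -1.17, 0.35, -0.67 and -0.57.

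The count for DMBA against acetone rests on single arrays: it was 65, 22 and 59 without acetone replicate 1, 2 and 3, 56 without DMBA replicate 2 and 820 without DMBA replicate 3. Median scaling left 3 genes, 1 higher and 2 lower, beside 128 higher and 58 lower.

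With BaP, the secreted iron-binding protein gene Ltf fell most, with a log2 change of -4.12 (SE 0.09, adjusted p = 2.06e-22), from 10.88 ± 0.09 to 6.76 ± 0.10 (mean ± SD, n = 3). Padi1 (-2.90), the antigen-presenting H2-K1 (-2.88) and the secreted proteins Wfdc2 (-2.07), Sftpd (-1.74) and Lcn2 (-1.58) also fell. Serpinb2, a protease inhibitor gene, rose 4.53-fold (2.18, SE 0.08, adjusted p = 2.65e-16), and Cdkn1a rose 2.40-fold (1.26). In all, 1891 genes passed, 842 higher and 1049 lower, and 256 of them changed at least 1.5-fold. Over all genes tested, 24.6% had no overlap between the arrays of both groups, against 10% by chance.

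Further increases with BaP were those of Hnrnpa2b1 (1.65), Calr (1.40), Brat1 (1.38), H2-Ea (1.35), Adss (1.33), Hspa8 (1.32), Ddx5 (1.31) and Dynll2 (1.27). Further decreases were those of Prcp (-2.14), Sprr2f (-1.83), Cstdc4 (-1.39) and Tenm4 (-1.32). Dimmer probes of Hnrnpa2b1 gave 0.15 and 0.04, those of Brat1 gave -0.12 and -0.05, and single dimmer probes gave -0.03 for Ddx5, -0.16 for Dynll2 and -0.24 for Ltf. Those of Brat1, Ddx5, Dynll2 and Ltf lay near the lowest signals, at mean levels from 5.90 to 6.29, where little of a change can show. Dimmer probes of Cdkn1a, at mean levels of 8.13 and 7.76, gave 0.65 and 0.97. Dimmer probes of other genes gave 0.28 and 0.09 for Ugt1a6a, -0.09 for Nqo1, 0.11 and 0.03 for Fbln2, 0.05 and 0.21 for Fbln1, -0.05 and 0.0083 for Ddx4, 0.33 and 0.09 for Fas, and -0.51 and -0.02 for Vegfa. Several of these also lay near the lowest signals, such as that of Nqo1 at a mean level of 5.95 and those of Ddx4 at 6.25 and 5.87. Of 13 aryl hydrocarbon receptor battery genes, the conjugating enzyme Ugt1a6a (1.22), the quinone reductase Nqo1 (0.52) and the receptor's repressor Ahrr (0.28) rose, 3 also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.111). Cyp1a1 (-0.01) and Cyp1b1 (0.13) did not pass. Of 24 phase I and II metabolism genes, 4 rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.563), and median scaling turned the list median from 0.01 to -0.38. They include Akr1c18 (0.70) and Ephx1 (0.50) among the higher and Gstt2 (-0.56) among the lower genes.

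Of 40 p53 targets, 9 rose and 1 fell with BaP (11 and 2 adjusted over the list alone, camera adjusted p = 0.00102), led by Cdkn1a, Phlda3 (0.93), Trp53inp1 (0.57) and the death receptor gene Fas (0.49). With an estimated correlation the adjusted p = 0.141, and under median scaling the median of the list turned from 0.10 to -0.14. Of 27 macrophage and leukocyte genes, none rose and 12 fell (12 adjusted over the list alone, camera adjusted p = 7.03e-09), led by Coro1a (-1.21), Cd52 (-1.08), Cx3cr1 (-0.83) and Tyrobp (-0.64), and the adjusted p = 0.0562 with an estimated correlation. Of 28 hypoxia and glycolysis genes, 7 fell (11 adjusted over the list alone, camera adjusted p = 0.00102), among them Aldoa (-0.65), Ndrg1 (-0.55) and the angiogenic factor gene Vegfa (-0.50), with adjusted p = 0.144 with an estimated correlation. Of 23 unfolded protein and heat shock genes, 5 rose (5 adjusted over the list alone, camera adjusted p = 0.0382), with adjusted p = 0.204 with an estimated correlation, and under median scaling the median turned from 0.08 to -0.31.

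Of 23 inflammation genes, 5 rose and 7 fell with BaP (6 and 7 adjusted over the list alone), and of 34 interferon response genes 1 rose and 2 fell, also adjusted over the list alone. Neither list passed against other genes (camera adjusted p = 0.617 for inflammation and 0.756 for interferon response), while fry, which does not compare a list with other genes, gave adjusted p = 0.0114 and 0.0053. Under median scaling the inflammation list passed, with a median of -0.24 (adjusted p = 0.0293).

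Of 51 oocyte genes, 3 rose and 12 fell with BaP (4 and 14 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0617). Oosp1 (-0.97), the growth factor gene Bmp15 (-0.86), Rfpl4 (-0.55) and Gdf9 (-0.34) fell and Spin1 (0.82) rose, while Zp3 (0.26) did not pass. Of 34 granulosa genes, 2 rose, among them the transcription factor Foxl2 (0.44), and 7 fell, among them the steroid enzyme Hsd17b1 (-0.66), with 2 and 9 adjusted over the list alone (camera adjusted p = 0.111). Of 26 stroma genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0871), with Fbln2 at 1.01 and the collagen gene Col3a1 at 0.82, and median scaling turned the median of the stroma and mesenchyme list from 0.03 to -0.23. The germ cell gene Ddx4 rose by 0.47 and Hmox1 fell by 0.39. Mdm2 (-0.09), Bax (-0.09), Amh (-0.08), Foxo3 (0.03), Akt1 (-0.01), Actb (0.25) and Gapdh (-0.24) did not pass, and median scaling put Actb at -0.12 and Zp3 at -0.11. Foxo3 and Akt1 lay near the lowest signals, at mean levels of 6.01 and 6.14.

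BaP arrays were dimmer than the others, and median scaling gave 5130 calls, 253 higher and 4877 lower, with a median shift of -0.38 among genes above the median level and -0.05 over all genes. Under median scaling Fas was at 0.013 and Ephx1 at 0.018. The count for BaP against acetone was 1082 without acetone replicate 2.

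**Figure D1:**
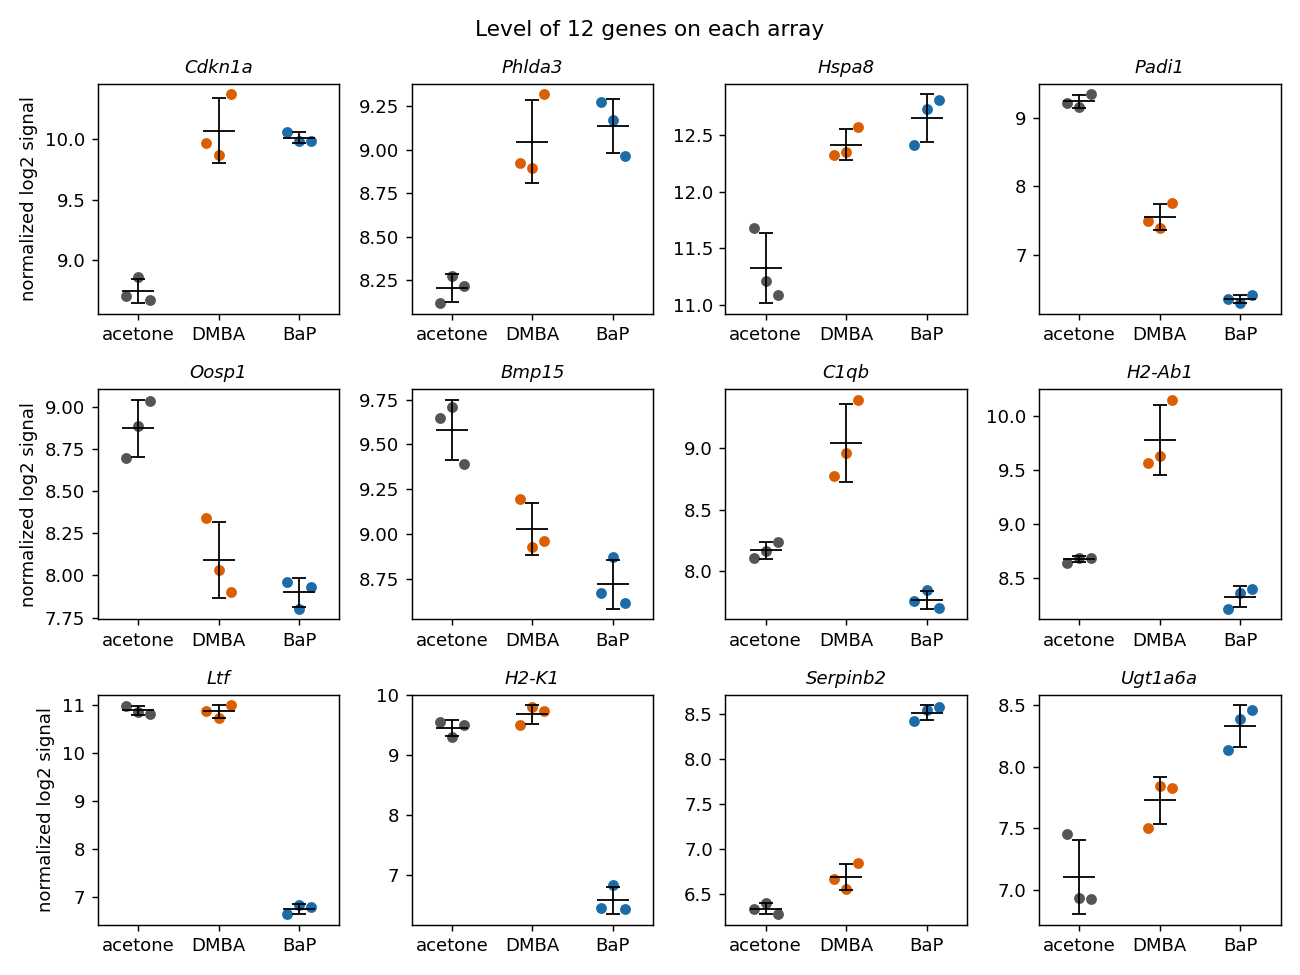
Normalized log2 signal (y axis) of 12 genes on each of the 9 arrays, by group (x axis); points are arrays, bars the mean and SD of 3. Ltf lay at 10.88 with acetone and 6.76 with BaP, and Cdkn1a at 8.75 with acetone, 10.07 with DMBA and 10.01 with BaP.

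DMBA is a methylated benzanthracene and BaP an unmethylated benzopyrene, and they were given at different doses, 50 nM and 1 uM, so their responses stand side by side and not at a matched dose. Compared directly, Ltf (-4.11), H2-K1 (-3.11), Sftpd (-2.17), Lcn2 (-1.95), the antibacterial Pglyrp1 (-1.93), Wfdc2 (-1.92), H2-T23 (-1.72), Sprr2f (-1.72), Prcp (-1.68) and Rpusd4 (-1.60) were lower with BaP than with DMBA. Serpinb2 (1.83), the purine enzyme Xdh (1.24), OTTMUSG00000025408 (1.17), the growth factor Gdf10 (1.01), Akr1c18 (0.92), Mid1 (0.87), Defb48 (0.83), Spon2 (0.82), the haem synthesis gene Alas2 (0.79) and the chemokine Cxcl12 (0.78) were higher. Dimmer probes gave 0.01 and 0.08 for Mid1, 0.25, 0.37, 0.03 and 0.10 for Cxcl12, and -0.69 for H2-T23. Those of Mid1 had low mean levels of 6.44 and 5.91, and those of Cxcl12 at 0.03 and 0.10 had levels of 5.88, where little of a change can show. In all, 261 genes passed, 121 higher and 140 lower with BaP, and 124 differed at least 1.5-fold. The arrays of both groups did not overlap in 16.9% of all genes tested, against 10% by chance.

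Of 27 macrophage and leukocyte genes, 13 were lower with BaP than with DMBA and none higher (17 adjusted over the list alone, camera adjusted p = 2.51e-19, and adjusted p = 0.0194 with an estimated correlation), led by C1qc (-1.13), Cd52 (-0.92), Coro1a (-1.06) and C1qb (-1.28). Of 28 hypoxia and glycolysis genes, 4 were lower (8 adjusted over the list alone, camera adjusted p = 1.54e-09, and adjusted p = 0.0257 with an estimated correlation), namely Vegfa (-0.69), Adm (-0.62), Ndrg1 (-0.70) and Aldoa (-0.65). Of 34 interferon response genes, H2-K1, B2m (-0.54) and Igtp (-0.55) were lower (9 adjusted over the list alone, camera adjusted p = 1.29e-06, and adjusted p = 0.0335 with an estimated correlation). Of 23 inflammation genes, 2 were higher and 3 lower (5 and 9 adjusted over the list alone, camera adjusted p = 0.00218), with Ccl5 at -1.05 and Cxcl1 at 0.60, and of 26 genes of the stroma and mesenchyme list 2 were higher (6 adjusted over the list alone, camera adjusted p = 6.44e-04), Fbln2 (0.51) and Fbln1 (0.50). Without DMBA replicate 3, 9 hypoxia and glycolysis genes were lower, 5 stroma genes were higher, and 3 inflammation genes were higher and 5 lower. For the inflammation and stroma lists, the adjusted p = 0.0941 with an estimated correlation, and the median of the stroma list turned from 0.15 to -0.085 under median scaling.

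Other responses did not pass the direct test, which does not show that they were equal. Of 40 p53 targets limma called 0 between the compounds, over all genes or adjusted over the list alone (camera adjusted p = 0.879), beside 2095 genes of all at an unadjusted p under 0.05, and called 2 p53 targets higher with BaP without DMBA replicate 3. The difference for Cdkn1a was -0.06 (95% interval -0.32 to 0.21), for Mdm2 0.01 (-0.17 to 0.20), for Bax -0.24 (-0.54 to 0.06) and for Nqo1 0.32 (0.15 to 0.49, adjusted p = 0.0868). Median scaling gave 2072 genes, 53 higher and 2019 lower with BaP, beside 121 and 140. The count for BaP against DMBA was 774 without DMBA replicate 3, 85 without DMBA replicate 2, and 86, 90 and 77 without BaP replicate 1, 2 and 3.

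Fold changes against acetone correlated between the compounds at r = 0.545 across genes, which are not independent replicates. Both use the same 3 acetone arrays, and unchanged groups simulated against them gave r = 0.375 (central 95% of 1000 draws 0.361 to 0.391). The covariance was 0.015, against a simulated 0.00372. Of the genes called with both, 92 rose and 44 fell with both, against 6.02 and 3.4 for independent lists, and 11 went opposite ways. This overlap rests on the 186 DMBA calls. Of these, 22 stayed called without acetone replicate 2, 55 without DMBA replicate 2 and 3 under median scaling. With 3 acetone arrays no split into groups of at least 2 was possible, and part or all of the excess may come from the shared controls.

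**Figure D2:**
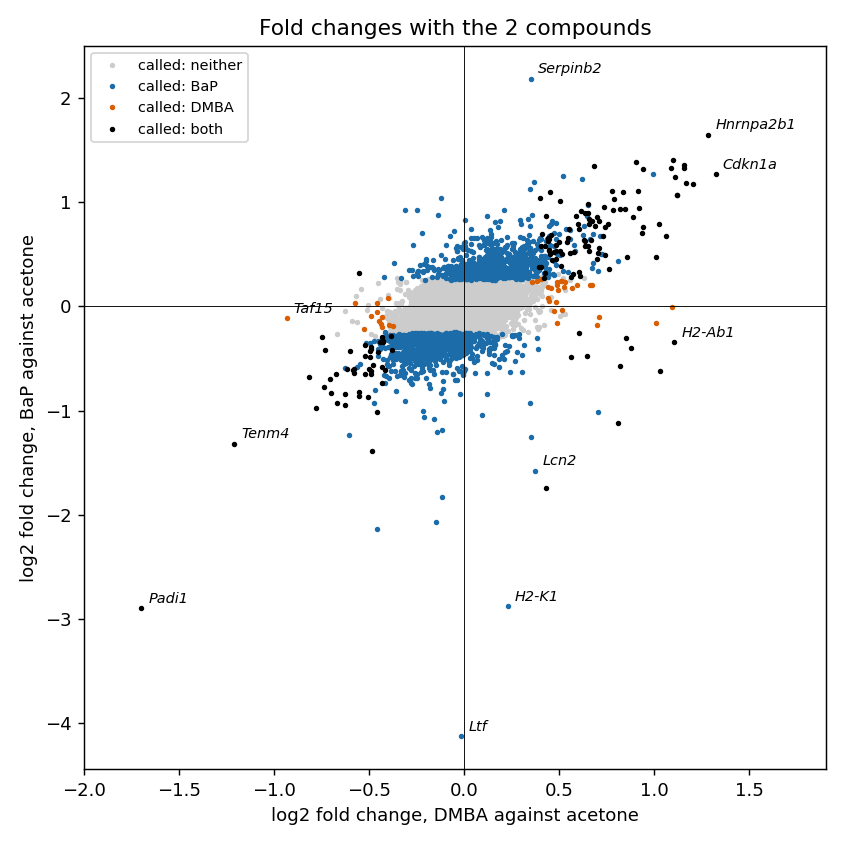
Log2 fold change with BaP (y axis) against that with DMBA (x axis), each against acetone, for 17889 genes, coloured by which compound the gene was called with. The genes called with both lie mainly in the lower left and upper right (44 and 92 genes), and Ltf and H2-K1 lie low on the BaP axis, with DMBA changes of -0.02 and 0.23.

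**Figure D3:**
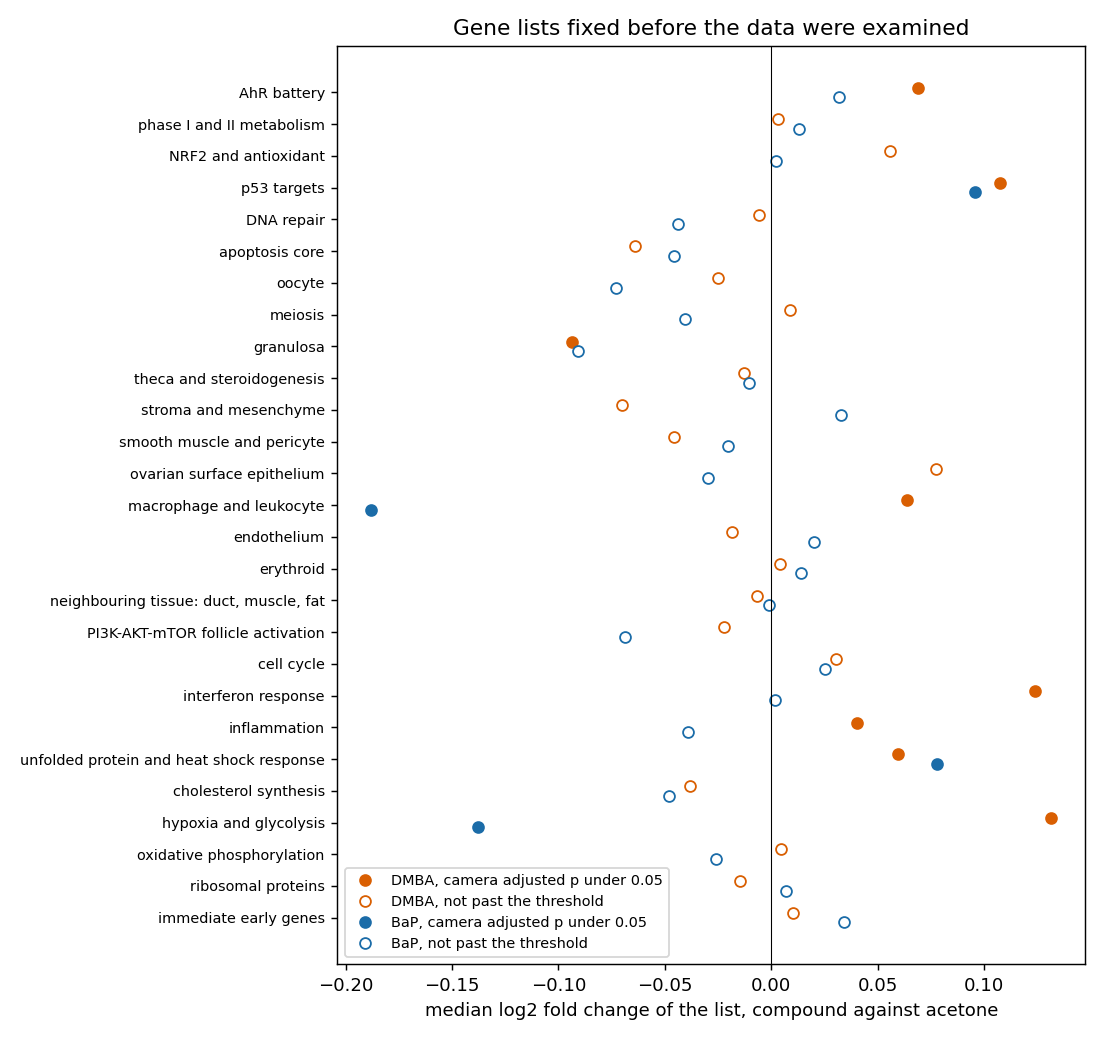
Median log2 fold change against acetone (x axis) of 27 gene lists (y axis) with DMBA and BaP; filled points passed camera with the preset correlation. Macrophage and leukocyte genes lay at 0.06 with DMBA and -0.19 with BaP.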

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

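The tests of shared arrays, other probes, leukocyte markers and epithelial markers were chosen after the results were seen. The tests of brightness, histocompatibility probes and oestrogen-induced genes were written before theirs. The decision rules for oestrogen-induced genes and epithelial markers were made more cautious after their values were seen.

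In 11 genes called against acetone with both compounds the effects went opposite ways, and each differed in the direct test between the compounds. That test used the same DMBA and BaP arrays, and choosing opposite effects makes a difference likely, so it is no separate support. BaP minus DMBA was -1.28 for C1qb, -1.13 for C1qc, -1.05 for Ccl5, -1.39 for Cd74, -1.45 for H2-Ab1, -0.86 for Lgals3, -1.65 for LOC641240, 0.87 for Mid1, -1.93 for Pglyrp1, -2.17 for Sftpd and -1.16 for Tspan8. For Mid1 this rests on the brightest probe: its dimmer probes, at low mean levels of 6.44 and 5.91, were at 0.09 and 0.06 with DMBA and 0.10 and 0.14 with BaP. Dimmer probes of H2-Ab1 differed: the probe at level 8.12 also went opposite ways, at 0.78 with DMBA and -1.07 with BaP. The probe at level 7.67 rose with both, at 1.10 with DMBA and 0.29 with BaP. Among gene lists, the median difference between the compounds was 0.15 for stroma and mesenchyme, -0.43 for macrophages and leukocytes, -0.11 for interferon response, -0.15 for inflammation and -0.20 for hypoxia and glycolysis.

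A set of 136 genes changed the same way with both compounds. The set is bounded by the 186 DMBA calls, of which 22 stayed called without acetone replicate 2 and 3 under median scaling. Brightness of the arrays stays open. Slopes on brightness within groups predicted a median share of 0.0453 of the BaP change (95% bootstrap interval 0.01 to 0.0842). Genes are called for a change that is large beside their spread within groups, so a small share was partly set in advance. Only the brightness gap of BaP (-0.58 log2 units) was used, and that of DMBA was -0.05. Another 20 probes of 15 of these genes moved by a median share of 0.745 of the called probe, which argues against a signal of single probes as the whole cause. It stays open for Ahnak, Hexdc and Srsf5, whose other probe moved by shares of 0.206, 0.234 and -0.246, and for the genes with no second probe above the level limit of 7.5. The covariance exceeded the simulated one by 0.0113, so the spread between the acetone arrays does not account for all of it. That spread may be technical, and the simulation holds no deviation that the acetone arrays have in common. The shared arrays may thus account for part or all of the overlap, and a response common to the compounds remains a hypothesis.

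Among macrophage and leukocyte genes 12 were lower with BaP. Histocompatibility genes, for which no list was fixed, went both ways: H2-K1 (-2.88), H2-T23 (-1.02) and H2-Ab1 (-0.34) were lower and H2-Ea (1.35), H2-K2 (0.63) and H2-Q7 (0.41) higher. Dimmer probes gave -1.07 and 0.29 for H2-Ab1 and -0.016 for H2-T23. Fewer leukocytes of every type would lower all their markers, while loss of 1 type would lower only its own. The list mixes markers of several types. The 19 leukocyte markers above the median level changed by a median of -0.41, the lowest being Coro1a at -1.21, and all 19 fell by less than H2-K1 by over 2 standard errors. Dimmer markers had less room to fall before the lowest signals, and no allowance for background was made, so part of this gap was set in advance. The mean level was 8.57 for H2-K1, 8.58 for C1qc (-0.48) and 7.99 for Coro1a. These are means over all 9 arrays, BaP included, so H2-K1 started higher and room to fall was not matched. Cd68 (-0.04, mean level 8.14) and Ms4a7 (-0.10, mean level 8.12) lay above the lowest signals and changed little. This argues against an even loss of all leukocyte types as the whole cause for H2-K1. Loss of 1 type was not tested and stays open. For the macrophage and leukocyte genes themselves fewer leukocytes stay open as a cause. A sequence variant under the probe, possible in outbred mice, cannot be told apart from a change in level: only 1 histocompatibility gene, H2-Ab1, has several bright probes, which spread over 1.36 log2 units with BaP and 0.32 with DMBA (one-sided Fisher exact p = 0.0744 against 88 of 1195 other genes, the smallest p that 1 gene allows, so this test decides nothing). A response to BaP itself was not tested further.

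Ltf, Wfdc2, Sprr2f, Sftpd, Lcn2 and Padi1 were lower with BaP, a set picked after its values were seen with no enrichment test, and Padi1 was also lower with DMBA (-1.70). Less adjoining epithelium may contribute. With BaP, 7 epithelial markers changed by a median of -0.22 (95% bootstrap interval -0.37 to -0.14), with 3 called lower and 1 higher (Krt19 -0.63, Cldn4 -0.37, Esrp1 0.27). The list was lower than other genes (camera unadjusted p = 0.0023, preset correlation), and its median with DMBA was 0.01. But 4 of them are also on ovarian lists, whose baseline would hide a small share, so this cannot be told apart from a change within the cells. A lower oestrogen response is likewise open: 9 oestrogen-induced genes changed by a median of 0.14 (95% bootstrap interval -0.10 to 0.47), going both ways, and 1 of them, Cdkn1a, is also a p53 target. By the rule first written, a median that was not negative spoke against it. The interval was asked for after the values were seen.

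For each comparison, 3 arrays against 3 allow 10 splits, too few for a share under 0.05, and 1 of 10 gave as many calls, the real one. The real counts were 186 with DMBA, 1891 with BaP and 261 between the compounds, and the highest of the other splits was 0 in each.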

How the results depend on the processing

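The cause of these differences was not tested except where fewer genes or samples were used. For DMBA against acetone (186), the count was 98 with the deposited values, 116 without background correction, 3 with median scaling, 56 in the brightest 25% of genes, 297 with all 9 arrays in one fit, 900 with array weights, 106 by fold of 1.5 and the unadjusted p of the plain test, 91 by limma's adjusted p and that fold, and 0 by the plain test after adjustment. That test was run on the same values, where limma gave 1828 genes at an unadjusted p under 0.05. Leaving out a replicate gave 22 to 820. For BaP against acetone (1891), it was 5130 with median scaling, 1000 in the brightest 25%, 1081 in one fit, 107 by the plain test, 254 by fold and the plain test's unadjusted p and 256 by limma's adjusted p and fold, and 1082 to 1787 without a replicate. For BaP against DMBA (261), it was 2072 with median scaling, 74 in the brightest 25%, 458 in one fit, 1058 with array weights, 1 by the plain test, 130 by fold and the plain test's unadjusted p and 124 by limma's adjusted p and fold, and 77 to 774 without a replicate. The correlation of DMBA and BaP fold changes, 0.545, ran from 0.472 to 0.59 without a replicate.

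Replicate numbers do not pair the samples: same-numbered deviations correlated at 0.0553, 0.0514 and 0.139 between acetone and DMBA, -0.145, 0.0176 and -0.111 between acetone and BaP, and -0.131, -0.0155 and -0.186 between the compounds. Not every sample correlated best with its own number. With a replicate block the counts were 210 for DMBA against acetone, 1481 for BaP against acetone and 136 for BaP against DMBA, and the unfolded protein and heat shock response list with BaP had an adjusted p of 0.0524.

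Under median scaling, called BaP changes turned to -0.083 for Aldh1a1, -0.14 for Atp5a1, -0.10 for Atp5c1, -0.019 for Cdca8, -0.037 for Cyp51, -0.0072 for Gstm6, -0.10 for Hspe1, -0.020 for Igf1, -0.11 for Pdia6, -0.0555 for Rpl3, -0.21 for Rplp0 and -0.068 for Serpine2. The direction of the list test turned to lower for these lists, with medians of -0.38 for phase I and II metabolism, -0.14 for p53 targets, -0.31 for unfolded protein and heat shock response, -0.48 for cholesterol synthesis and -0.26 for ribosomal proteins with BaP, -0.14 for ribosomal proteins with DMBA, and -0.085 for stroma and mesenchyme, -0.30 for cell cycle, -0.19 for unfolded protein response and -0.31 for cholesterol synthesis between the compounds. With that scaling, all genes above the median level had a median of -0.38 with BaP, -0.09 with DMBA and -0.29 between the compounds. Lower medians under it are therefore not particular to these lists. No other setting reversed a called gene or list. Without a replicate, these lists lost their call. With DMBA, the adjusted p of the AhR battery (aryl hydrocarbon receptor) was 0.0528 without DMBA replicate 1 and 0.0622 without DMBA replicate 2, that of granulosa genes 0.051 without acetone replicate 2 and 0.0627 without DMBA replicate 1, that of inflammation 0.0528 without DMBA replicate 1, and that of unfolded protein response 0.0567 without acetone replicate 3, 0.394 without DMBA replicate 1 and 0.122 without DMBA replicate 2. With BaP, that of unfolded protein response was 0.0698 without BaP replicate 2, 0.073 with the deposited values and 0.0627 without background correction. Among genes above the median level, the adjusted p with DMBA was 0.113 for granulosa, 0.053 for inflammation and 0.053 for unfolded protein and heat shock response, which fry put at 0.268. Of values of single named genes under the alternatives, 151 with DMBA, 104 with BaP and 133 between the compounds lost the call, while 946, 1707 and 1023 kept their direction and side of the threshold. With no detection p-values, signal over background could not be set per probe.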

Other observations

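Groups not described above also held changed members with BaP. Of 37 cell cycle genes, 4 rose and 4 fell, among them Mcm7 (0.84) and Ccnd2 (0.67) higher and Bub1b (-0.44) lower. Of 24 meiosis genes, Smc1b fell by 0.70, and Mnd1 (0.61) and Dnmt3l (0.35) rose. Of 18 cholesterol synthesis genes, Insig1 rose by 0.95 and Nsdhl by 0.76 with BaP, and by 0.74 and 0.74 with DMBA. Dimmer probes with BaP gave 0.56, 0.88 and -0.07 for Insig1 and 0.64, 0.50 and 0.16 for Nsdhl, and with DMBA 0.43, 0.64 and 0.02 for Insig1 and 0.71, 0.44 and -0.0088 for Nsdhl. Of 20 immediate early genes, Egr2 (0.73) and Fos (0.42) rose with BaP. None of these lists passed camera in either comparison against acetone. Of 52 DNA repair genes, 2 rose and 7 fell with BaP, among them Polh (0.37) higher and Brca2 (-0.35) lower, and of 35 core apoptosis genes 2 rose, Fas and the receptor gene Tnfrsf1a (0.58), and 4 fell, among them Bik (-0.61) and Casp9 (-0.44). Neither list passed (camera adjusted p = 0.717 and 0.953). Median scaling turned the BaP medians of the cell cycle list from 0.03 to -0.34 and of the immediate early genes list from 0.03 to -0.15. Of 24 genes of the NRF2 and antioxidant list, 2 rose and none fell with DMBA (camera adjusted p = 0.0576, and 4 rose without DMBA replicate 3), and 4 rose and 2 fell with BaP (camera adjusted p = 0.99).

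A probe of Tmem14c, named here after its values were seen, differed from the others of that gene. Its change with BaP was -2.94 on the log2 scale, while brighter probes of the gene were at -0.05 and -0.20.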
